A study of Mus musculus with 6 samples.

How the data were processed

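Gene expression was measured by poly(A) RNA-seq in whole lungs of 6 mouse embryos at E18.5, 3 with a wild type genotype label and 3 with a Prmt5 knockdown label. Per the labels' protocols, RNA was extracted on columns, polyadenylated RNA was captured on oligo(dT) beads, fragmented and copied with random primers, and the libraries were read as paired ends. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 without their roles or settings. The genome build and the strand setting are not given in the sources used here.

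The deposited table holds raw counts per gene and library, and, per the file headers, the FPKM of each gene and library together with its exonic length. The deposited FPKM values were recomputed from the count, the library's total count and the exonic length, and agreed within 0.005 for every entry. Gene identifiers, symbols and coordinates are those of the table. Its coordinates differ from those of the GRCm38 annotation for most genes, so they are printed as given with no build named, and no coordinates were converted. Gene biotypes were taken by identifier from the GENCODE M21 annotation, in which 52083 of the 55359 genes were found. Each row of the table names a gene, and no row of unassigned reads entered the totals.

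Before the data were examined, the design, the rule for naming genes, 52 gene lists for lung cell types, other tissues and pathways, and the alternatives were fixed. The test fixed for a table of FPKM values was limma on log2(FPKM + 1). The same plan made edgeR's quasi-likelihood test the one to use if raw counts were present. Since they were, edgeR 4.0.16 was run in R 4.3.3 on the counts as deposited, with filterByExpr at its defaults (17728 genes kept), TMM normalization and a model with the group as its only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F, and confidence intervals are at 95%. Means and SDs are of CPM computed with the TMM factors over the 3 libraries of a group. For genes without counts in a group the fold is a lower bound against 3 counts over that group, and for genes with 1 to 3 counts the ratio has an exact 95% counting interval. An exact permutation test of 3 against 3 libraries cannot go below a p of 0.1, so single genes were not tested that way.

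The gene lists, with 997 distinct genes of which 939 were tested, were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2, at its preset correlation of 0.01, and all 52 had at least 5 tested members. The test was repeated with a correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance. Adjusted p-values of lists cover all 52. Counts adjusted over a list alone come from the edgeR p-values of that list's members. The hypoxia and glycolysis list counts 30 entries for 29 symbols because a symbol stands on 2 rows of the table. Some genes are on more than 1 list.

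Genes named are Prmt5, the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, up to 10 genes in each direction, and up to 4 members with the smallest p in each list spoken of. The 10 per direction are called genes with groups that do not overlap and with a symbol that is not a predicted or unnamed model (Gm with a number, an ending in Rik or -ps, or an identifier), ordered by size of change. As only 1 gene qualified in each direction, the rest were filled with the smallest p and are given as not past the threshold. Other genes are said to be chosen after their values were seen.

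Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-of-ratios and quantile scaling, totals without erythroid, mitochondrial and the 20 most abundant genes, limma without the trend or with robust estimation, robust edgeR, library weights, leaving out each library, DESeq2 1.42.0 and a minimum absolute log2 fold change of 1. The pseudocount, trend, robust limma and library weight alternatives are limma fits to log2 FPKM of genes with a mean FPKM of at least 1, and median-of-ratios scaling was applied to the counts. Alternatives added after the data were seen are embryo sex as a covariate, the mean level of the heart muscle list as a covariate, an adjusted p of 0.10, and the limma fit to log2(FPKM + 1) as a stand-alone result.

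Total counts ranged from 14383415 to 19262837 per library, so a floor of 3 counts corresponds to 0.156 to 0.209 CPM. The common biological coefficient of variation was 21.8%. The fits were tested on counts simulated from these libraries' means, depths and gene-wise dispersions, with 194 changed genes among 17479. Genes were drawn independently and without tissue differences inside a group, so recovery and false calls may differ in the real libraries. In the simulated comparison of knockdown-labelled with wild type libraries edgeR recovered 52.0% of changes of 1 on the log2 scale and 89.6% of changes of 2, with 9 false calls among 146. On the same data limma recovered 51.0% and 90.6% with 8 false calls among 145, and DESeq2 70.4% and 92.7% with 54 among 212. In a simulation of the lists the shifted list was called and 0 unshifted ones were. As its genes were drawn independently, it does not test the preset correlation for lists whose genes move together. Estimated correlations in the real libraries were 0.654 for general endothelium, 0.362 for alveolar type 1, 0.768 for heart muscle and 0.792 for nuclear oxidative phosphorylation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.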

Results

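Poly(A)-selected RNA was sequenced from whole lungs of 6 C57 mouse embryos at E18.5, late gestation. Of these 3 were labelled wild type and 3 were labelled Prmt5 knockdown. Prmt5 is the main enzyme that adds symmetric dimethyl groups to arginines of histones and spliceosomal proteins. The series text speaks of a Prmt5 knockout in the lung mesenchyme that is specific to Dermo1, another name of Twist2. The sample labels use the word knockdown. RNA of the whole organ also holds transcripts of epithelium, endothelium and blood cells. Wild type replicates 1, 2 and 3 had 16358478, 14383415 and 15544572 counts assigned to genes. Knockdown-labelled replicates 1, 2 and 3 had 16100007, 14390202 and 19262837. Of 55359 genes in the table, 17728 had enough counts to be tested. Within each group the libraries differed by more than counting noise, so none was counted as a repeat of another. The labels do not say whether the embryos came from separate litters. The p-values therefore measure the spread between these samples, which may in part be technical.

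Sex-linked transcripts showed that both sexes were present in each group. Xist, the RNA that silences an X chromosome in females, had 34, 19641 and 22929 counts in wild type replicates 1 to 3 and 32, 17662 and 18 in knockdown-labelled replicates 1 to 3. The Y-linked gene Ddx3y had 1950, 0 and 2 counts in wild type and 2190, 1 and 2078 in the knockdown-labelled libraries. In the 3 libraries with high Ddx3y, counts were 1711 to 1964 for Eif2s3y, 1112 to 1320 for Kdm5d and 670 to 797 for Uty, against 0 to 4, 0 and 0 to 2 in the others. By these genes 1 wild type and 2 knockdown-labelled embryos were male.

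The targeted gene was measured first. Prmt5 (ENSMUSG00000023110, chromosome 14, 54744644 to 54754982, minus strand) stood at 46.7, 47.3 and 48.3 CPM (counts scaled to the same library total) in wild type and at 39.6, 47.8 and 46.9 CPM in the knockdown-labelled libraries. The group means were 47.4 ± 0.777 and 44.7 ± 4.49 CPM (SD, n = 3 each), a log2 fold change of -0.08 (95% confidence interval -0.29 to 0.13). This did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.682). Without knockdown-labelled replicate 1 the log2 fold change was 0.0069. The counts are per gene and do not resolve single exons, so the loss of part of the transcript was not analysed here. Cells outside the mesenchyme also contribute Prmt5 RNA. The interval leaves room for a small drop. Because no drop of the gene passed the test in whole-lung RNA, the groups are called wild type and knockdown-labelled throughout. Every direction below rests on the labels. The 12 measured members of the list of Prmt5 partners and other arginine methyltransferases had a median log2 fold change of -0.05 (camera adjusted p = 0.657). Of these 0 passed the threshold over the list alone and 1 had an unadjusted p under 0.05, Riok1 (42.8 ± 1.75 against 36.6 ± 1.09 CPM). The Sm and Lsm proteins, of which several are Prmt5 substrates in spliceosome assembly, had a median of 0.05 (adjusted p = 0.60).

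The comparison of the 2 groups asks which transcripts of the late fetal lung differ when Prmt5 is targeted in the mesenchyme. Wnt5a, a secreted signal of the lung mesenchyme, fell 1.69-fold in the knockdown-labelled lungs. Genes of endothelial cells and of alveolar type 1 cells, the thin gas-exchange epithelium, were lower as groups, by medians of -0.41 and -0.39 on the log2 scale. Nuclear genes of oxidative phosphorylation were higher by a median of 0.47, or 0.13 with heart muscle level as a covariate. Genes of heart muscle were higher by 2.21, or 4.05 without wild type replicate 3. These 4 lists passed camera at its preset correlation and none passed with an estimated one (adjusted p = 0.612 for each). Surfactant and other alveolar type 2 genes and the genes of the cell cycle did not pass the test as groups.

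Across all genes 6 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1 higher and 5 lower. At an unadjusted p under 0.05 there were 3015, where 886.4 would be met on average if no gene differed. Genes that move together make such a count vary widely, and it was not taken for other groupings of the 6 libraries. The 3015 are therefore not evidence of an effect of the label. Wnt5a (ENSMUSG00000021994, chromosome 14, 28226707 to 28249405) went from 67.3 ± 2.69 to 39.8 ± 1.65 CPM (SD, n = 3 each). Its log2 fold change was -0.76 with a standard error of 0.07 and an edgeR adjusted p of 0.0414. All 3 knockdown-labelled libraries lay below all 3 wild type ones. Olfr1033 (ENSMUSG00000045392, chromosome 2, 85850977 to 85875515), an olfactory receptor gene, had 0 counts in every wild type library and 175, 124 and 165 in the knockdown-labelled ones. It was at least 144-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0156). The other 4 were outside the naming rule and were picked after their values were seen. Gm8399, a processed pseudogene on chromosome 13, fell from 159 ± 58.3 to 7.93 ± 0.795 CPM (edgeR adjusted p = 0.0121). Glo1-ps, a processed pseudogene of the glyoxalase gene Glo1 on chromosome 2, fell from 7.40 ± 0.660 to 1.09 ± 0.0952 CPM (edgeR adjusted p = 0.0143). Gm10503 on chromosome 17 had 531 counts over the wild type libraries and 2 over the knockdown-labelled ones, all in replicate 3. The depth-corrected ratio was 285 with a 95% counting interval of 78.6 to 2363 (edgeR adjusted p = 0.0121). Gm50250, also on chromosome 17, had 207 and 3 counts, a ratio of 74.2 with an interval of 25.03 to 363 (edgeR adjusted p = 0.0213). With a library left out the log2 fold change of Gm10503 ranged from -10.46 to -7.43, against -7.92 with all. That of Gm50250 ranged from -6.92 to -5.62, against -6.06 with all. Pseudogenes can share reads with their parent genes. Gm10503 and Gm50250 overlap Glp1r and Btbd9 in the table's coordinates, and no strand setting is stated for the counts, so these 4 values are uncertain. Intervals and floors cover counting error only.

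DESeq2 called 373 genes higher and 457 lower, among them all 6 above. On data simulated with independent genes DESeq2 made 54 false calls among 212, against 9 among 146 for edgeR. With a library left out in edgeR, 0 genes passed without wild type replicate 1 or 2 or knockdown-labelled replicate 1 or 2 (1663 to 3287 at an unadjusted p under 0.05). There was 1 without knockdown-labelled replicate 3 and 17 without wild type replicate 3. Wnt5a had an edgeR adjusted p of 0.0569 to 0.224 in these fits. With embryo sex as a covariate 0 passed (2524 unadjusted). With heart muscle level as a covariate 1 passed, and 1234 had an unadjusted p under 0.05 against 3015 without it. Heart muscle RNA was higher in every knockdown-labelled library than in every wild type one, so that covariate also takes up part of the label's difference. The smaller counts therefore do not show heart muscle as the source of the differences.

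**Figure D1:**
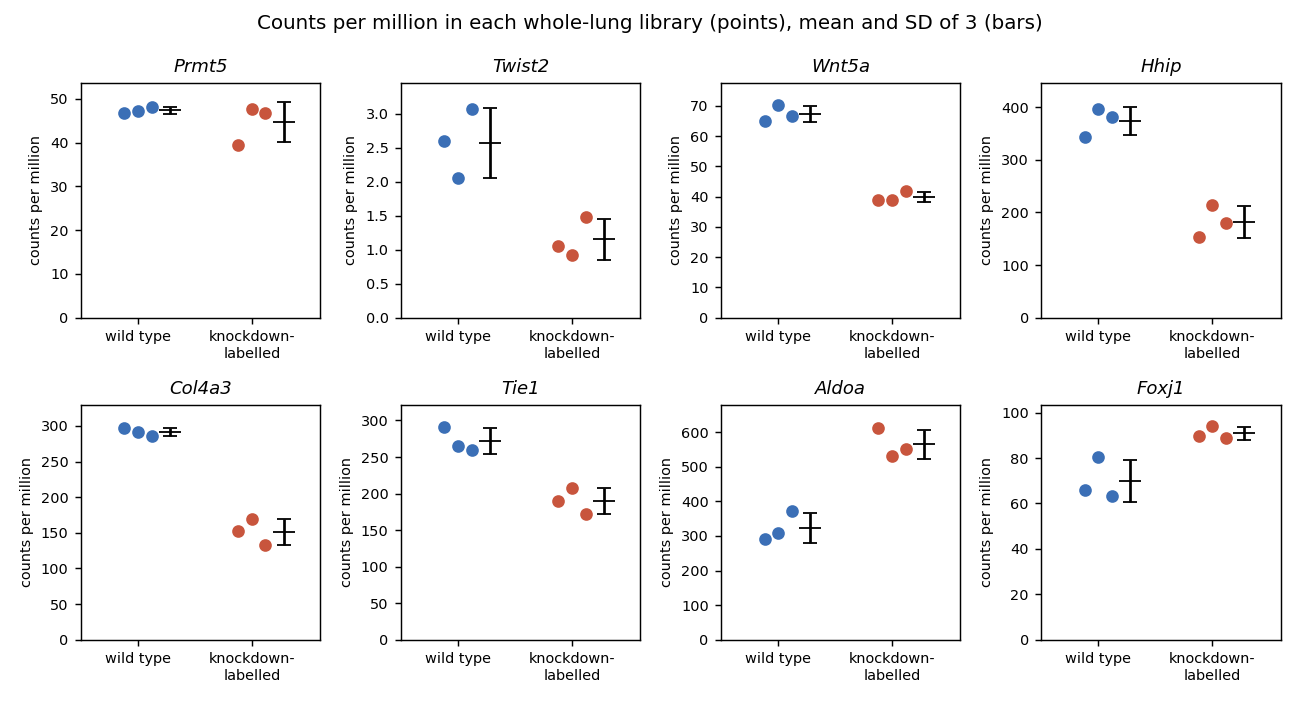
CPM (y axes, starting at 0) of 8 genes in the 3 wild type (blue) and 3 knockdown-labelled (red) whole-lung libraries, with each library as a point and the group mean ± SD as a black bar. Prmt5 overlaps between the groups (means 47.4 and 44.7), Wnt5a does not (67.3 and 39.8), and Wnt5a alone among the 8 passed an edgeR adjusted p of 0.05 over all genes.

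Single genes of the myofibroblast list and of pathway lists were lower in the knockdown-labelled lungs, while these lists as wholes did not pass. In the list of myofibroblasts and smooth muscle, 5 of 29 measured members were lower adjusted over the list alone and 1, Wnt5a, over all genes tested. Beside Wnt5a they included Hhip, the Hedgehog-binding inhibitor (374 ± 26.8 against 182 ± 30.5 CPM), Foxf1, a mesenchymal transcription factor (218 ± 19.12 against 139 ± 23.8 CPM), and the matrix gene Tgfbi (214 ± 7.34 against 139 ± 24.1 CPM). As a whole that list did not pass (median 0.20, camera adjusted p = 0.991). Of 14 Hedgehog pathway genes 4 were lower adjusted over the list alone and 0 over all genes. These were Hhip and Foxf1 again, the ligand Shh (84.8 ± 7.54 against 66.9 ± 5.70 CPM) and the receptor Ptch1 (198 ± 12.1 against 156 ± 19.5 CPM), and the list median was -0.07 (adjusted p = 0.0635). Of 25 Wnt pathway genes 3 were lower adjusted over the list alone and 1 over all genes. They were Wnt5a, Wnt2 (51.5 ± 6.21 against 33.7 ± 2.27 CPM) and Rnf43 (44.2 ± 1.84 against 36.2 ± 1.54 CPM). The list median was 0.14 (adjusted p = 0.864). Among 29 BMP and TGF-beta genes Bmp5 alone was lower over the list alone (50.5 ± 2.04 against 36.5 ± 3.30 CPM), with 0 over all genes and a list median of -0.12 (adjusted p = 0.310). The FGF and retinoic acid list had a median of 0.09 (adjusted p = 0.778).

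Fibroblast genes of the alveolar wall fell as a group. The list of lipofibroblasts and alveolar matrix fibroblasts had a median of -0.26 with 21 of 25 members negative (camera adjusted p = 2.95e-05, but adjusted p = 0.612 with an estimated correlation). The call was lost with the heart muscle level described below as a covariate (median -0.14, adjusted p = 0.0613). Adjusted over the list alone 11 were lower and 1 higher, and over all genes 0. The integrin ligand Npnt stood at 825 ± 25.4 against 533 ± 45.5 CPM and the fatty acid transporter gene Slc27a6 at 155 ± 8.98 against 90.8 ± 19.2 CPM. Lpl, which encodes lipoprotein lipase and is also on the capillary list, was the higher member (122 ± 16.9 against 248 ± 46.2 CPM). Its highest value, 295 CPM, was in knockdown-labelled replicate 2, the library with the most heart muscle RNA, so the cells behind its rise were not resolved. Pericyte and vascular smooth muscle genes had a median of -0.20 (adjusted p = 0.0215, and adjusted p = 0.612 with an estimated correlation). Without wild type replicate 2 the camera adjusted p was 0.0743, and with the heart muscle covariate 0.452 (median -0.14). Of 22 members 5 were lower and 1 higher adjusted over the list alone and 0 over all genes. Its lower members included Pde5a (404 ± 24.0 against 282 ± 20.3 CPM) and Gucy1a1 (405 ± 15.4 against 294 ± 27.4 CPM), both of the nitric oxide and cGMP pathway. Its higher one was the potassium channel subunit gene Abcc9 (51.6 ± 2.02 against 78.8 ± 5.82 CPM). Elastic fibre and collagen genes had a median of -0.10 (adjusted p = 0.0311, and adjusted p = 0.612 with an estimated correlation). Of 32 members 5 were lower and 1 higher adjusted over the list alone and 0 over all genes. Without wild type replicate 2 and without knockdown-labelled replicate 2 the median was -0.055 and -0.054 (camera adjusted p = 0.116 and 0.189), and with the heart muscle covariate -0.045 (0.436). Ltbp2 stood at 237 ± 3.97 against 178 ± 8.37 CPM there and Emilin2 at 14.8 ± 2.07 against 30.3 ± 5.73 CPM. Adventitial fibroblast genes did not pass (median 0.28, adjusted p = 0.889). Twist2 is on that list, with 2.57 ± 0.515 against 1.15 ± 0.296 CPM. Its log2 fold change of -1.14 missed the threshold over the list alone (adjusted p = 0.0633) and over all genes (edgeR adjusted p = 0.163).

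Endothelial genes fell together. All 24 measured genes of the general endothelium list had negative log2 fold changes, with a median of -0.41 (camera adjusted p = 6.29e-12, but adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone 18 were lower, and over all genes tested 0. The angiopoietin co-receptor gene Tie1 stood at 272 ± 17.3 against 190 ± 17.6 CPM, the junction gene Pecam1 at 635 ± 41.8 against 459 ± 52.9 CPM and Robo4 at 98.4 ± 6.51 against 73.9 ± 3.60 CPM. Genes of aerocytes, the capillary cells specialised for gas exchange, had a median of -0.44 with 12 of 13 negative (adjusted p = 5.62e-06, and adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone 9 were lower and over all genes 0. Prx stood at 193 ± 14.6 against 113 ± 13.1 CPM, Kitl at 285 ± 21.3 against 184 ± 27.4 CPM and the endothelin receptor gene Ednrb at 204 ± 7.49 against 150 ± 14.3 CPM. The general capillary list had a median of -0.26 (adjusted p = 0.0138, and adjusted p = 0.612 with an estimated correlation), and of -0.39 with heart muscle level as a covariate (adjusted p = 0.04905). Of 13 members 7 were lower adjusted over the list alone, such as Cd93 (505 ± 18.8 against 347 ± 58.2 CPM) and Tmem100 (80.8 ± 3.997 against 55.5 ± 7.62 CPM), 2 were higher, and 0 passed over all genes. Angiogenic factors had a median of -0.21 (adjusted p = 0.00886, and adjusted p = 0.612 with an estimated correlation). With the heart muscle covariate the call was lost at the same median (-0.21, adjusted p = 0.0672). Of these 10 of 25 were lower and 2 higher adjusted over the list alone, and 0 over all genes. Vegfc, a lymphangiogenic growth factor, stood at 16.2 ± 0.295 against 11.4 ± 0.889 CPM and the guidance gene Slit2 at 341 ± 45.4 against 223 ± 28.3 CPM. Larger vessels and lymphatics did not pass as groups. The arterial and venous list (median -0.01, adjusted p = 0.727) had 5 lower members, among them Gja4 and Sox17, and 3 higher adjusted over the list alone. The lymphatic list (median -0.06, adjusted p = 0.991) had 3 of each, with Lyve1 at 237 ± 31.1 against 165 ± 13.5 CPM. Prox1, the lymphatic master regulator, stood at 11.8 ± 3.85 against 26.3 ± 10.8 CPM. Its highest value, 38.7 CPM, was in knockdown-labelled replicate 2, the library with the most heart muscle RNA, so the source of its rise was not resolved.

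**Figure D2:**
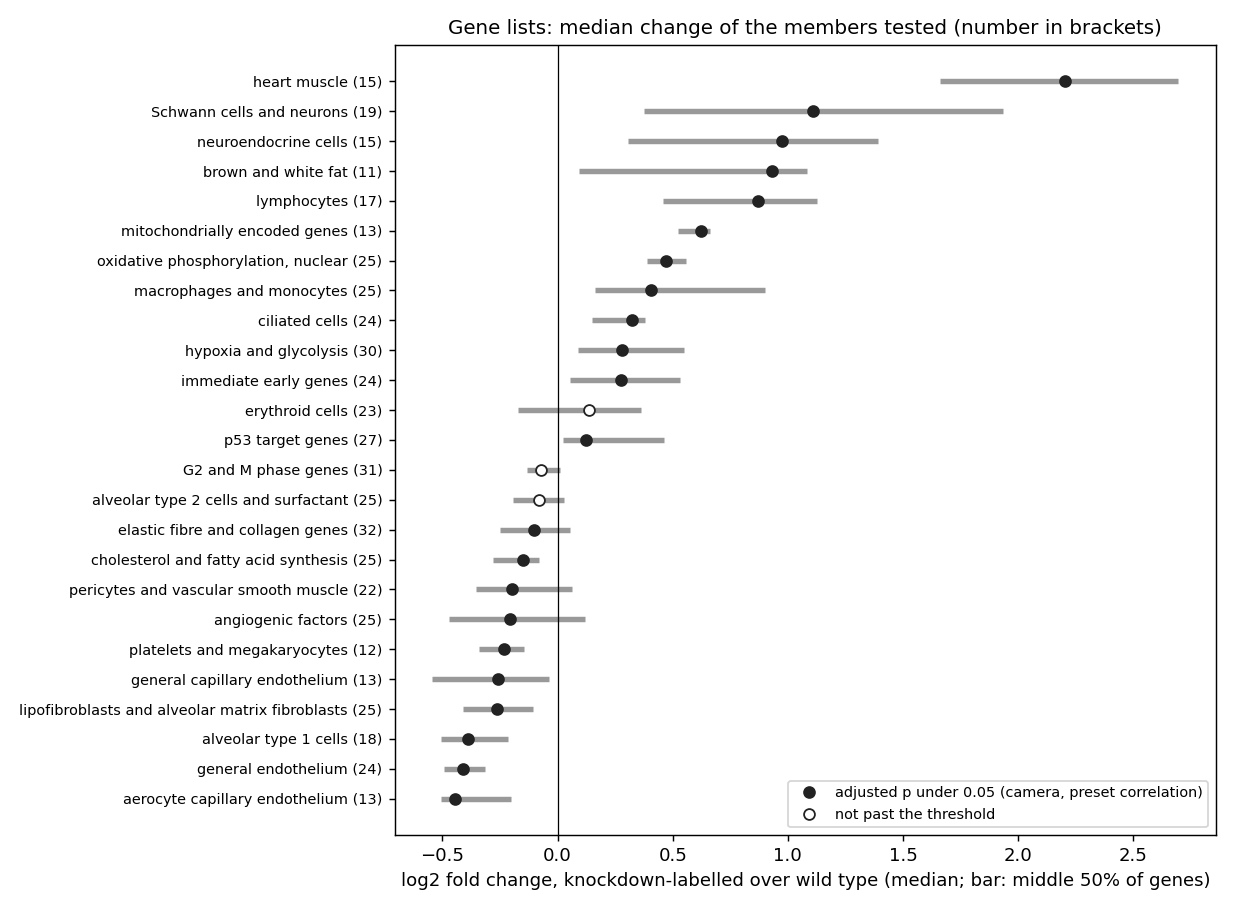
Median log2 fold change, knockdown-labelled over wild type (x axis), of the measured members of each gene list that passed the camera test at its preset correlation (filled points) and of 3 that did not (open points), with grey bars for the middle 50% of members. General endothelium (median -0.41) and alveolar type 1 cells (-0.39) lie at the low end, and heart muscle (2.21) at the high end.

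Within the epithelium, alveolar type 1 genes fell as a group and type 2 genes did not pass. Of 18 alveolar type 1 genes 17 were negative, with a median of -0.39 (camera adjusted p = 5.56e-07, but adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone 9 were lower, and over all genes 0. The basement membrane collagen genes Col4a3 (291 ± 5.87 against 151 ± 18.48 CPM, edgeR adjusted p = 0.0625) and Col4a4 (380 ± 8.72 against 224 ± 31.2 CPM) led the list, followed by the type 1 marker Ager (1393 ± 120.5 against 945 ± 83.9 CPM). Emp2, which is on the aerocyte list as well, stood at 1114 ± 84.1 against 785 ± 95.5 CPM. The 25 alveolar type 2 and surfactant genes had a median of -0.08 (adjusted p = 0.310). Of these 0 passed the threshold over the list alone and 2 had an unadjusted p under 0.05, Ppp1r14c and Sfta2, both with higher means. Distal tip progenitor genes (median 0.03, adjusted p = 0.223) and club cell genes (0.27, adjusted p = 0.0635) did not pass either. Fmo2 was the club cell gene lower over the list alone (839 ± 58.0 against 602 ± 41.3 CPM). Genes of ciliated cells rose as a group, with 23 of 24 positive and a median of 0.32 (adjusted p = 6.63e-07, but adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone 7 were higher and over all genes 0. Among the 7 were Foxj1, the transcription factor of motile cilia (69.8 ± 9.22 against 90.9 ± 2.80 CPM), and Ccdc40, which assembles the axoneme (30.0 ± 2.06 against 37.4 ± 0.824 CPM).

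Genes of energy metabolism rose as groups, together with those of heart muscle. All 25 nuclear oxidative phosphorylation genes were positive with a median of 0.47 (camera adjusted p = 2.44e-11, but adjusted p = 0.612 with an estimated correlation). Without knockdown-labelled replicate 2 the median was 0.31 and the list still passed. Adjusted over the list alone 24 were higher, and over all genes 0. Uqcrfs1 of complex III stood at 58.1 ± 5.59 against 85.6 ± 11.3 CPM and the cytochrome oxidase gene Cox5a at 24.6 ± 2.81 against 40.6 ± 8.89 CPM. The 13 mitochondrially encoded genes had a median of 0.62 (adjusted p = 0.0218, and adjusted p = 0.789 with an estimated correlation). Of these 0 passed the threshold over the list alone and 0 had an unadjusted p under 0.05. The camera call was lost without wild type replicate 1 or 2 (adjusted p = 0.0566 and 0.129) or knockdown-labelled replicate 3 (0.0959), and without knockdown-labelled replicate 2 the median was 0.20 (0.440). Genes of heart muscle, a tissue that in mice also sheathes the large pulmonary veins, were all positive with a median of 2.21 (adjusted p = 5.79e-07, but adjusted p = 0.612 with an estimated correlation). Without wild type replicate 3 the median was 4.05. Of 15 members 9 were higher adjusted over the list alone and 0 over all genes. Their share of all counts was 0.0407%, 0.0528% and 0.254% in wild type replicates 1, 2 and 3. It was 0.374%, 1.07% and 0.286% in knockdown-labelled replicates 1, 2 and 3, where the ventricular light chain gene Myl2 reached 958 CPM in knockdown-labelled replicate 2. With the heart muscle level as a covariate the oxidative phosphorylation median was 0.13 (camera adjusted p = 0.0306) and the mitochondrially encoded median -0.07 (0.436). Hypoxia and glycolysis genes had a median of 0.28 (adjusted p = 0.000436, but adjusted p = 0.636 with an estimated correlation). Of 30 entries 4 were higher adjusted over the list alone and 0 over all genes. They were the glycolytic enzymes Aldoa (324 ± 44.0 against 565 ± 42.1 CPM) and Tpi1 (196 ± 29.9 against 337 ± 14.05 CPM), the lactate exporter gene Slc16a3 and Pdk1. Without knockdown-labelled replicate 1 the list median was 0.11 (camera adjusted p = 0.174). With the heart muscle covariate it was not smaller, at 0.36 (camera adjusted p = 8.99e-05). Cholesterol and fatty acid synthesis genes fell as a group, by a median of -0.15 (adjusted p = 0.00728, but adjusted p = 0.636 with an estimated correlation). Of 25 members 0 passed over the list alone and 4 had an unadjusted p under 0.05. The camera call was lost without wild type replicate 1 (adjusted p = 0.0653) or knockdown-labelled replicate 1 (0.0919), and with the heart muscle covariate (median -0.12, 0.483).

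**Figure D3:**
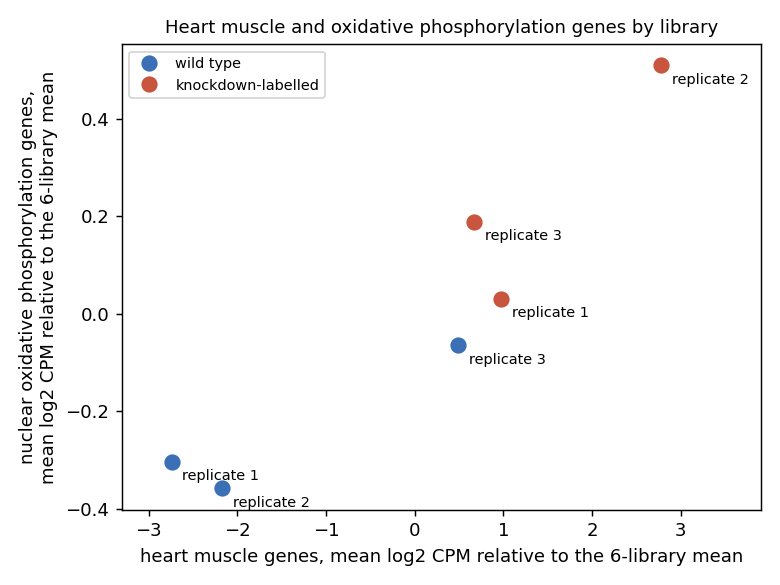
Mean log2 CPM of nuclear oxidative phosphorylation genes (y axis) against that of heart muscle genes (x axis), each relative to the mean of the 6 libraries, with wild type in blue and knockdown-labelled in red. Knockdown-labelled replicate 2 is highest on both axes (2.78 and 0.51), and wild type replicates 1 and 2 are lowest on both.

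The cell cycle lists did not pass the test and the p53 list passed it. The lists of S phase genes (median 0.04, camera adjusted p = 0.991) and of G2 and M phase genes (-0.07, adjusted p = 0.315) did not pass. Of 25 and 31 members 0 and 0 passed over the list alone, and 1 and 0 had an unadjusted p under 0.05. Genes activated by p53 had a median of 0.12 with 21 of 27 positive (adjusted p = 0.0353, but adjusted p = 0.612 with an estimated correlation). Of these 0 passed over the list alone and 6 had an unadjusted p under 0.05. The leading ones were Ccng1 (75.2 ± 13.1 against 120.3 ± 20.8 CPM) and Eda2r (1.74 ± 0.610 against 3.99 ± 1.35 CPM). The camera call was lost without wild type replicate 1 (adjusted p = 0.0909), knockdown-labelled replicate 2 (0.0525) or knockdown-labelled replicate 1, where the median was 0.066 (0.114). It was also lost with the heart muscle covariate, at a larger median (0.16, adjusted p = 0.199).

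The naming rule also filled each direction with the genes of smallest p that missed the edgeR threshold, and all of these had groups that did not overlap. On the higher side, with adjusted p from 0.0715 to 0.0804, they were Olfr1034, Hmga1, Mt1, Abcc9, Aldh1l2, Nr1d1, Fads6, Mif and Ccn1. Olfr1034, the neighbour of Olfr1033 on chromosome 2, had 0 counts in wild type and was at least 25.1-fold higher against the same floor, and the others had log2 fold changes of 0.61 to 1.66. Hmga1, a chromatin architectural protein gene of fetal tissues, stood at 23.1 ± 2.38 against 42.6 ± 4.38 CPM, the mitochondrial folate enzyme gene Aldh1l2 at 4.88 ± 1.24 against 13.9 ± 0.284 CPM and the circadian repressor gene Nr1d1 at 13.0 ± 0.430 against 20.9 ± 0.748 CPM. On the lower side, with edgeR adjusted p from 0.0625 to 0.0715, they were Col4a3, Glo1, Svep1, Tmem204, Ism1, Ptgs1, Egflam, Itga1 and Nes, with log2 fold changes of -0.94 to -0.57. The matrix gene Svep1 stood at 213 ± 13.7 against 126 ± 9.06 CPM, the collagen-binding integrin gene Itga1 at 307 ± 23.9 against 186 ± 11.04 CPM and Glo1 at 100.5 ± 3.18 against 64.1 ± 3.04 CPM. At an adjusted p of 0.10 edgeR listed 32 genes higher and 64 lower.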

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

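The covariate fits, the threshold of 0.10 and the limma fit to log2(FPKM + 1) were chosen after seeing the data. The main counts of 1 gene higher and 5 lower were kept within 1.5 times by that limma fit, median-of-ratios scaling, totals without the abundant genes, limma without the trend or with robust estimation, and a minimum change. Other settings gave other counts, and the cause was not tested except where fewer genes or libraries entered. With pseudocounts of 0.1 and 0.5 limma called 0 higher, and 3 lower with 0.1 (2653 and 2660 genes at an unadjusted p under 0.05). Without a filter 32 genes were higher and 49 lower, and at a mean FPKM of at least 5, which keeps 9005 genes, 0 and 2. Quantile scaling gave 3 and 17, robust edgeR 14 lower, library weights 8 and 16, and DESeq2 373 and 457. At an adjusted p of 0.10 there were 32 and 64. With sex as a covariate there were 0 and 0 (2524 at an unadjusted p under 0.05), and with heart muscle level 0 and 1 (1234). Leaving out a library gave 0 to 13 higher and 0 to 4 lower: 0 in all without wild type replicate 1 or 2 or knockdown-labelled replicate 1 or 2, 1 lower without knockdown-labelled replicate 3, and 13 higher and 4 lower without wild type replicate 3. Wnt5a stayed negative in 21 of 21 alternatives (log2 fold change -0.79 to -0.62) and passed in 6, with adjusted p from 5.32e-10 to 0.702.

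Prmt5 passed in 0 of 21 alternatives. Its log2 fold change ranged from -0.13 to 0.0069 when a library was left out, the sign turning without knockdown-labelled replicate 1. The 22 lists called by camera became 15 to 26 under the other fits, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by fry (11 at an unadjusted p under 0.05). Medians of the general endothelium (-0.49 to -0.35), alveolar type 1 (-0.49 to -0.30) and nuclear oxidative phosphorylation lists (0.13 to 0.57) kept their sign in all 21 alternatives and lost the camera call only with an estimated correlation. With heart muscle level as a covariate the medians of the lymphocyte and mitochondrially encoded lists turned to -1.50 and -0.072, and the platelet median went to -0.73 and the general capillary one to -0.39, both still called. Over all list medians 77 values lost the call, and among single genes 51 lost and 64 gained it, with the direction kept. DESeq2 was not followed by a list test. No paired analysis was possible because the numbers in the titles are not shared between the groups. The heart muscle covariate, added after the data were seen, also ended the camera calls of the pericyte (median -0.14, adjusted p = 0.452), elastic fibre and collagen (-0.045, 0.436), immediate early (0.063, 0.714), fat (0.53, 0.0752) and cholesterol (-0.12, 0.483) lists. The angiogenic factor (-0.21, 0.0672) and p53 lists (0.16, 0.199) lost it without a smaller median. As heart muscle level overlaps with the label, a call lost with this covariate does not show heart muscle as the source of a difference. At this depth and with 3 libraries per group edgeR recovered 52.0% of simulated changes of 1 on the log2 scale, and smaller ones were not simulated. The simulation held independent genes without the tissue differences seen among these libraries, so recovery in the real libraries was not measured.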

Other observations

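Some lists of immune, nerve and fat genes passed camera at its preset correlation, and none of them with an estimated one. Macrophage and monocyte genes rose as a group (median 0.41, 21 of 25 positive, camera adjusted p = 0.000154, but adjusted p = 0.612 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone and 0 over all genes. The Fc receptor gene Fcgr1 stood at 0.887 ± 0.269 in wild type against 3.54 ± 0.478 CPM in the knockdown-labelled libraries, and Fabp4, which is also on the fat list, at 18.6 ± 5.71 against 49.8 ± 14.2 CPM. Fabp4 was highest, at 65.9 CPM, in knockdown-labelled replicate 2, the library with the most heart muscle RNA, so the cells behind its rise were not resolved. Neuroendocrine genes had a median of 0.98 (adjusted p = 0.000711, but adjusted p = 0.636 with an estimated correlation), with 3 of 15 higher over the list alone and 0 over all genes, among the 3 Uchl1 (2.56 ± 1.02 against 9.82 ± 2.65 CPM) and the granin gene Chgb (1.02 ± 0.241 against 6.45 ± 3.87 CPM). Schwann cell and neuron genes had a median of 1.11 (adjusted p = 0.00360, but adjusted p = 0.636 with an estimated correlation), with 6 of 19 higher over the list alone, such as the neuronal filament genes Nefm and Prph, 1 lower (Ednrb) and 0 over all genes. Without knockdown-labelled replicate 3 the neuroendocrine median was 0.56 and the Schwann cell and neuron median 0.48, which lost the call (adjusted p = 0.127), and without wild type replicate 3 the latter was 1.71. In knockdown-labelled replicates 1 to 3 the mean levels were 0.60, -0.27 and 1.09 for the neuroendocrine list. They were 0.60, -0.37 and 1.11 for the Schwann cell and neuron list, so the 2 rises may not be separate. Brown and white fat genes had a median of 0.93 (adjusted p = 0.0215, and adjusted p = 0.612 with an estimated correlation) with Fabp4 as the member higher over the list alone. The fat median was 0.61 without wild type replicate 1, 0.59 and 0.50 without knockdown-labelled replicates 2 and 3, and 0.76 without knockdown-labelled replicate 1, which ended the call (adjusted p = 0.0803), as did the heart muscle covariate (0.53, 0.0752). Immediate early genes had a median of 0.28 (adjusted p = 0.0486, and adjusted p = 0.636 with an estimated correlation), led by Ccn1 (101.6 ± 12.1 against 170 ± 12.8 CPM), the single member past the threshold over the list alone. That call was lost without wild type replicate 1 (median 0.25, adjusted p = 0.0761) or 2 (0.17, 0.169) or knockdown-labelled replicate 1 (0.18, 0.174) or 2 (0.20, 0.189), and with the heart muscle covariate (0.063, 0.714). Platelet genes had a median of -0.23 (adjusted p = 0.0486, and adjusted p = 0.636 with an estimated correlation), or -0.73 with that covariate (adjusted p = 0.000612). Without the covariate 0 of 12 passed the threshold over the list alone and 0 had an unadjusted p under 0.05. The list kept the call without wild type replicate 1 and without knockdown-labelled replicate 2 (median -0.40) and lost it without wild type replicate 2 (adjusted p = 0.370) or 3 (0.369) or knockdown-labelled replicate 1 (median -0.061, 0.350) or 3 (0.0695).

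Genes of other tissues were high in some libraries of both groups. Lymphocyte genes had a median of 0.87 (adjusted p = 0.00951, but adjusted p = 0.636 with an estimated correlation), with 0 of 17 past the threshold and 0 at an unadjusted p under 0.05. Their mean level, relative to all 6 libraries, was -1.20, -2.12 and 1.27 in wild type replicates 1 to 3 and 1.25, 1.70 and -0.90 in knockdown-labelled replicates 1 to 3. The list median was 4.43 without wild type replicate 3 and 0.53 without replicate 1, and the call was lost without wild type replicate 2 (0.37, adjusted p = 0.269) or knockdown-labelled replicate 1 (0.81, 0.0803) or 2 (0.33, 0.0769). With heart muscle level as a covariate the median turned to -1.50 and the call was lost (adjusted p = 0.141). Among genes chosen after their values were seen, the skeletal myosin gene Myh8 reached 675 CPM in wild type replicate 3 and 1611 CPM in knockdown-labelled replicate 3, and the liver gene Alb 72.1 CPM in knockdown-labelled replicate 3. The basal keratin gene Krt5 stood at 38.8 and 39.1 CPM in those 2 libraries and at most at 6.36 CPM in the others. The remaining lists did not pass camera: skeletal muscle (median 1.38, adjusted p = 0.0743), liver (1.82, 0.423), basal cells (0.44, 0.240), esophagus, skin and thyroid (0.36, 0.620), mast cells and basophils (1.26, 0.240), neutrophils (0.27, 0.310), erythroid cells (0.14, 0.495), cartilage (0.51, 0.513), mesothelium (0.09, 0.540), germline genes (0.04, 0.935), sex-linked genes (0.95, 0.889) and cytosolic ribosomal proteins (0.02, 0.961). Nor did heat shock (0.19, 0.0730), the unfolded protein and integrated stress response (0.16, 0.151) and interferon response genes (-0.19, 0.0730).

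The tests below were chosen after the data were seen, except the splits of the libraries. For the sex and heart muscle covariates on the endothelial and type 1 genes, only the bounds were written before that outcome was seen. Groups of 3 and 3 libraries can be split in 10 ways, too few for a share under 0.05. The labelled split gave 6 calls, 3 of the 10 splits gave at least as many, and the highest other gave 42. That split sets wild type replicates 1 and 2 and knockdown-labelled replicate 3 against the rest, as the lymphocyte levels do, and 7 of its 42 genes are on the lymphocyte list, which points to a structure of the samples apart from the labels. The split by embryo sex gave 6 calls, 5 of them on the sex-linked list.

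The first pattern is the higher oxidative phosphorylation genes. A candidate explanation is heart muscle taken with the lung: with the heart muscle level as a covariate the list median went from 0.472 to 0.126 (camera adjusted p = 0.0306), and in each group the library with the most heart muscle RNA had the highest oxidative phosphorylation level. Myl2 and Myl3, which mark ventricular muscle and not the muscle sleeves of the pulmonary veins, stood at 958 and 322 CPM in knockdown-labelled replicate 2, but in replicates 1 and 3 Myl2 stood at 6.79 and 35.7 CPM with Myh6 at 1442 and 1140 CPM, so vein muscle stays open there. A difference by genotype at equal heart muscle level was 0.139 with a standard error of 0.166 and cannot be told apart from none, since every knockdown-labelled library had more heart muscle RNA than every wild type one. Knockdown-labelled replicate 3 lay above replicate 1 in oxidative phosphorylation (0.19 and 0.03) with less heart muscle (0.67 and 0.98), so heart muscle may not be the whole source. The mean level of the skeletal muscle list was 2.62 in knockdown-labelled replicate 3, 0.50 in replicate 1 and -1.33 in replicate 2. A share of skeletal muscle in this pattern was not tested.

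The second pattern is the lower endothelial and alveolar type 1 genes, with a median of -0.410 over both lists. Dilution by other tissue would lower alveolar type 2 genes alike, but relative to those the 2 lists were lower by a difference of -0.311 with a standard error of 0.081. Unequal numbers of male and female embryos are argued against by a median of -0.413 with sex as a covariate. With heart muscle level as a covariate the median was -0.429 and did not shrink. Every knockdown-labelled library had more heart muscle RNA than every wild type one, so that fit cannot separate heart muscle from the label. An effect of the targeted mesenchyme on neighbouring cells is a hypothesis that was not tested here and would need sorted cells. Differences in maturity or litter between embryos, RNA quality, and a change in cell numbers against a change per cell were not tested and stay open. Segments of the genome that differ between the embryos, raised below for the called genes, were not tested for these lists and stay open too.

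The third pattern is the large difference of most called genes: 5 of the 6 differed at least 6.70-fold, and 3 of those had at most 3 counts over a whole group. The genes named beside the calls were chosen after their values were seen. Of the 6 calls 0 lie within 10 Mb of Twist2 or Prmt5, which argues against a region of that size around either gene. Wnt5a is on chromosome 14, as is Prmt5, so a longer segment around Prmt5 is not excluded for it. Reads of Glo1 counted on Glo1-ps would keep their ratio if both groups carry the same Glo1 sequence. The ratio instead differed by -0.0566 with a standard error of 0.0038 (0.0736 in wild type, 0.0171 in knockdown-labelled). If the Glo1 sequence differs between the groups, this ratio cannot decide. Segments of the genome that differ between the embryos stay open as a source: with called genes within 1 Mb of each other counted once, 3 of 5 segments held a gene that was not called with an edgeR p under 0.001 within 1 Mb. Random genes gave 0.852 (0.0388 of 10000 draws reached 3), but the clustering was seen before the test and gives it little weight. On chromosome 17 Gm50250, Glo1 (log2 fold change -0.65), Dnah8 (-0.86), Gm50240 (-0.44) and Gm10503 lie between 30669372 and 31182194, as does part of Btbd9 (-0.40). In the same stretch Glp1r (0.02) and Gm50242 (-0.26) did not differ by more than their standard errors of 0.145 and 0.673. Below the calls, 5 of 123 tested genes within 10 Mb of Twist2 (4.07%) had an edgeR p under 0.001, against 145 of 17605 elsewhere (0.82%). Among those in the window were the adjacent type 1 genes Col4a3 and Col4a4. That window was looked at after these 2 had been seen, so it does not test linkage to the Twist2 locus, which stays open for them.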
